A study of Mus musculus with 6 samples.

How the data were processed

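Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in 6 libraries of mouse epiblast stem cells differentiated as embryoid bodies in serum for 2 days. Per the labels, 3 libraries came from Mixl1 knockout cells and 3 from Mixl1-inducible cells given doxycycline at 1 µg/mL for the last 24 h, each from 50000 cells and amplified with 11 PCR cycles. The labels call the libraries of a group triplicates and do not say whether they came from separate cultures.

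The deposited data used here were 2 peak lists in narrowPeak layout, 1 for each group, without a header. One is named KO and the other FM. No label explains FM, so it was set against the induced group by elimination, as the series has 2 groups and the other list is the knockout, and the text calls it the FM list. Per the submitters' processing notes the tools were bcl2fastq, Bowtie2, SAMtools and MACS2 and the build was mm10, with no versions. How the 3 libraries of a group were combined, whether reads were shifted for the Tn5 insertion site, and which filters on duplicate or mitochondrial reads were applied are not given in the sources used here. The authors' deposited values per peak are the fold enrichment of the summit over the local background, which is a ratio, and −log10 of the p-value and of the q-value. The lowest −log10 q in both deposited lists was 1.30, which is a q threshold of 0.05. These are the peak caller's own values and were used to describe, rank or filter peaks within a list.

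Rows with the same start and end, which are several summits of 1 peak, were collapsed to the row of lowest p-value, and peaks on the assembled autosomes, X and Y were kept. A peak was shared where it overlapped a peak of the other list by at least 1 bp, and specific otherwise. Regions are the merged union of both lists. Shares carry exact binomial (Clopper-Pearson) intervals at a confidence level of 95%, which cover the counting of peaks only. With 1 list per group there is no spread between replicates to set a difference against, and no test between the groups was made.

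Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes. The table used here has no strand, exons or transcript starts. The planned classes of promoter, exon and intron were therefore replaced by a summit within 1 kb of either end of a protein-coding gene, within a gene body, or intergenic. The planned nearest transcription start was replaced by the nearest protein-coding gene within 100 kb, with distance 0 inside the gene and ties counted for each gene. The planned scan for transcription factor motifs and the matching on GC content need the genome sequence, which was not used here, and were not run.

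For 10 gene lists of 180 genes fixed before the data were examined, the FM-specific share of the specific regions at the list's genes was placed among 10000 random lists of the same size, matched on the number of regions per gene. The percentiles were turned into two-sided permutation p-values and adjusted by the Benjamini-Hochberg method over the 10 lists of each setting, not over the settings tried. They describe these libraries and do not test the groups. The genes named are members of these lists and, outside them, the 12 genes whose specific regions deviated most toward each list among genes with at least 5 specific regions. The latter were ranked by the binomial probability of their split given the split over all specific regions. The single peaks named are the 5 of highest fold among the specific peaks of each list. Specific peaks of −log10 q of at least 10 near genes of the lists were added after the data were seen. Distances of single peaks from genes were taken from the summit.

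The depth in reads is unknown. The fold and p of a MACS2 peak together give its pileup and background, and the genome-wide background recovered from the fold values was 28.6 fragments in the FM list and 28.8 in the KO list, a ratio of 1.01. Pileups were recovered for 205663 of 205844 FM peaks and 138471 of 139164 KO peaks, and 99.99% of those recovered in each list were whole numbers within a tolerance of 0.02. The smallest peak width was 200 bp in both lists. These backgrounds compare depth only if both lists were called with the same fragment extension and genome size.

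The overlap functions, the random list procedure and the recovery of backgrounds were tested on simulated data. All of 20000 simulated peaks were classed as made. Random lists of 20 real genes were drawn from genes with several specific regions and scored by the unadjusted permutation p. Of these lists, 4% had p under 0.05 with no shift. After raising the FM-specific share by 10 percentage points 64% did, and after raising it by 15 percentage points 97% did. The fixed lists differ in size, hold genes with few or no specific regions and were judged on adjusted p. Shifts of this size and larger can therefore be missed in them. The alternatives tried were other definitions of overlap, stricter q and fold thresholds, equal numbers of peaks, the KO list thinned to the FM background, rows as deposited, all sequences, other assignments of regions to genes, and leaving out chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.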

Results

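Accessible chromatin was profiled in mouse epiblast stem cells, which are derived from the post-implantation epiblast, after 2 days as embryoid bodies in serum. The groups were Mixl1 knockout cells and cells in which Mixl1 was induced with 1 µg/mL doxycycline for 24 h, with 3 libraries each. Mixl1 is a homeobox transcription factor of the primitive streak that acts in mesendoderm formation. The comparison asks which regions were accessible with Mixl1 induced and which without Mixl1. The labels record doxycycline only for the induced group, and the groups are different cells, knockout and inducible. Effects of Mixl1, of doxycycline and of the cells used therefore cannot be told apart. Each group is represented by 1 peak list, so no value below has a replicate error. The list set against the knockout (KO) list is named FM and was taken as that of the induced group by elimination. The FM list held 205844 peaks on assembled chromosomes, covering 94.98 Mb, and the KO list 139164 peaks covering 67.6 Mb. Median widths were 345 bp and 352 bp, and the median fold enrichment was 1.96 in the FM list and 2.01 in the KO list. Depth in reads is unknown. The genome-wide background recovered from the peak values was 28.6 fragments for FM and 28.8 for KO.

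Mixl1 itself (gene ID 27217, chromosome 1: 180693043 to 180697034, mm10) had a peak over its end of higher coordinate in both lists. In the FM list this peak spanned 180696353 to 180697653 with a fold enrichment of 4.26 and −log10 q of 61.8. In the KO list it spanned 180696320 to 180697696 with a fold enrichment of 2.97 and −log10 q of 26.0. By fold the summit ranked 6323 among FM peaks and 20219 among KO peaks on assembled chromosomes, lists of different lengths. The KO list also had a weak peak inside the gene at 180695736 to 180696092, with a fold of 1.59. Of the regions assigned to Mixl1, 4 were shared, 0 were FM-specific and 2 were KO-specific, among them a peak at 180707335 to 180707765, 10.6 kb from the gene (fold 2.27). The FM list had peaks without a KO counterpart at 180687096 to 180687392 (fold 1.81) and 180687644 to 180687932 (fold 1.96), and the KO list had one without an FM counterpart at 180685311 to 180685519 (fold 2.02), all within 10 kb of Mixl1 but not assigned to it. Which part of Mixl1 was altered in the knockout is not given in the sources used here, so these peaks do not check the labels.

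**Figure D1:**
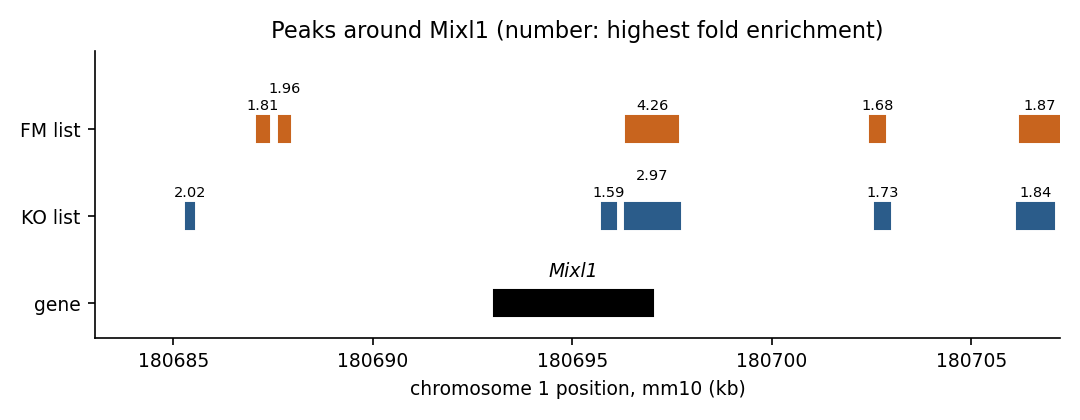
Map of chromosome 1 within 10 kb of Mixl1 (x axis, position in kb, mm10), with the gene in black, FM peaks in orange and KO peaks in blue, each with its highest fold enrichment within its own list. Both lists have a peak over the gene's right end, with a fold of 4.26 in FM and 2.97 in KO.

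Of the FM peaks, 101372 (49.2%, interval 49.0 to 49.5) overlapped a KO peak, and of the KO peaks 100923 (72.5%, interval 72.3 to 72.8) overlapped an FM peak. The merged lists made 239675 regions, of which 96962 were shared, 104472 FM-specific and 38241 KO-specific, so that FM-specific regions were 2.73 times as many. Specific peaks were mostly weak. Among peaks with −log10 q under 2, 22.1% of FM and 54.1% of KO peaks were shared, and among those over 50 the shares were 99.8% and 99.6%. At −log10 q of at least 10, 6163 FM and 3611 KO peaks had no peak in the other list. At 20 or more the order turned, with 200 FM-specific and 668 KO-specific peaks, or 23.0% FM-specific (interval 20.3 to 26.0). Where both lists were filtered first, a specific peak could still overlap a weaker peak of the other full list. In such settings 49.7% of specific peaks were FM-specific with 50000 peaks from each list, and 7.15% with a fold of at least 5. These shares are therefore not counts of peaks absent from the other list. Peaks of fold over 5 numbered 3723 (1.81%) in the FM list and 6689 (4.81%) in the KO list.

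**Figure D2:**
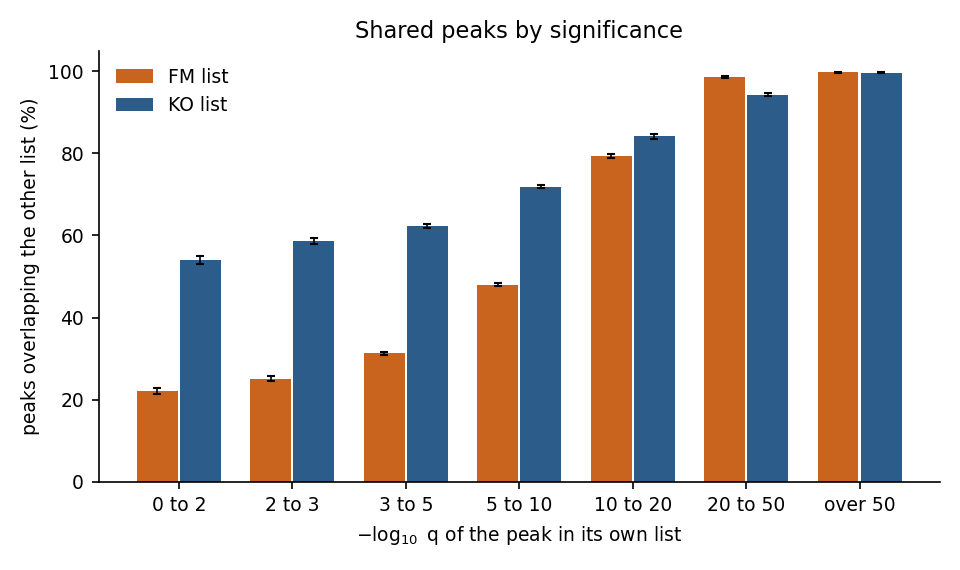
Percentage of peaks that overlap a peak of the other list (y axis) by the −log10 q of the peak in its own list (x axis), for the FM list in orange and the KO list in blue, with exact 95% binomial intervals as error bars. The share runs from 22.1% to 99.8% in the FM list and from 54.1% to 99.6% in the KO list.

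The 23 primitive streak and mesendoderm genes had 138 FM-specific and 44 KO-specific regions beside 204 shared ones, and 13 genes had more FM-specific and 4 more KO-specific regions. Lef1, a nuclear mediator of Wnt signalling, had 34 FM-specific and 4 KO-specific regions, and Gsc, a homeobox gene of the anterior streak, had 17 and 3. Eomes, a T-box gene of the streak, had 10 and 3, whereas T, encoding Brachyury, had 4 and 4. The list's FM-specific share was 75.8%, against a median of 74.4% in random lists (percentile 62.9). The difference from random lists in percentage points turned to −0.301 counting 10 kb around genes and −4.16 within 20 kb. It was −6.27 with −log10 q of at least 5 in both lists and −6.55 with 50000 peaks from each list. Among strong specific peaks, those with −log10 q of at least 10 and no peak in the other list, the streak genes had 5 FM and 12 KO peaks. This FM share of 29.4% stood against 66.7% in random lists, with an adjusted permutation p of 0.024, at a threshold chosen after the data were seen. The adjustment was over the 10 lists at this threshold and not over the settings tried. The KO peaks lay near T (17: 8447753 to 8448016), Nodal (10: 61406058 to 61406500), Evx1 (6: 52311321 to 52311729), Sp5 (2: 70491043 to 70491717), Wnt5a, Axin2, Lef1, Lhx1, Fgf8, Mixl1 and, with 2 peaks, Eomes. The strong FM peaks lay near Eomes (9: 118457853 to 118458116, fold 3.47), Lhx1 (11: 84549581 to 84550189, fold 3.08), Gsc, Fgf8 and Lef1.

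The 22 definitive endoderm genes had 169 FM-specific and 47 KO-specific regions, and 18 of them had more FM-specific regions. Cxcr4, a chemokine receptor of definitive endoderm, had 19 FM-specific and 0 KO-specific regions. The transcription factor genes Gata4, Foxa2 and Sox17 had 22 and 2, 10 and 1, and 6 and 0. Kitl went the other way with 1 and 4. Strong FM-specific peaks lay 1.68 kb from Foxa2 (2: 148048484 to 148049079) and near Gata4 and Cxcr4, and strong KO-specific peaks near Kitl, Krt19, Krt8 and Gata6. The FM-specific share of 78.2% was at percentile 87.3 of random lists, whose median was 73.4%. The direction against random lists turned with 50000 peaks from each list, with 21 FM-specific and 36 KO-specific regions.

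The 16 genes of Nodal and Activin signalling, the anterior mesendoderm and the node had 90 FM-specific and 29 KO-specific regions. Nog, a BMP antagonist, had 16 and 2, and Skil, a negative regulator of the pathway, had 1 and 5. A strong KO-specific peak lay near the Nodal target Lefty1 (1: 180933727 to 180934001). The FM-specific share was 75.6%, at percentile 64.6 of random lists, whose median was 73.5%. The direction against random lists turned with 50000 peaks from each list (37.5% against 48.7%) and with −log10 q of at least 5 in both lists (70.1% against 73.0%). It also turned among strong specific peaks (40% against 66.7%, from 4 FM and 6 KO).

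The 24 mesoderm and cardiac genes had the second highest FM-specific share of the 10 lists, 80.9%, with 199 FM-specific and 47 KO-specific regions, at percentile 97.6 of random lists with a median of 73.7%. Tbx5, a cardiac T-box gene, had 29 FM-specific and 4 KO-specific regions, Kdr, the VEGF receptor of blood and vessel progenitors, 24 and 3, and Foxf1 16 and 1. Pdgfra, a receptor of paraxial mesoderm, had 15 and 6, with strong FM-specific peaks at 5: 75174625 to 75174891 and 75176789 to 75177175 inside the gene. The direction against random lists turned with equal numbers of peaks, where 22 regions were FM-specific of 60. That share of 36.7% stood against 50.6% and lay at percentile 2.5 (unadjusted permutation p 0.0504, adjusted 0.252), about as far out on the other side. The direction also turned among strong specific peaks, with 7 FM and 5 KO or 58.3% against 65.0%. Matching random lists on chromosome gave percentile 93.2, and leaving out chromosomes 12, 15, 18, X and Y gave 93.1.

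The 21 pluripotency and epiblast genes had 179 FM-specific and 56 KO-specific regions (76.2%, percentile 65.5). Esrrb, a naive pluripotency factor, had 39 and 11, and 4 strong FM-specific peaks, of which the ones at 12: 86463891 to 86464140 and 86497090 to 86497552 lay inside the gene. Tfcp2l1 had 24 and 4. The KO list had a strong specific peak overlapping Nanog (6: 122707180 to 122707632, fold 2.87), with its summit 0.008 kb outside the gene. Another lay inside Fgf5, a marker of the primed epiblast.

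The 20 neurectoderm genes had 184 FM-specific and 53 KO-specific regions (77.6%, percentile 73.3). Irx3 had 28 and 5, Six3 19 and 4, and Pax3, a gene of the dorsal neural tube, 3 and 6. Strong KO-specific peaks lay near En1 (1: 120596511 to 120597085, fold 2.86), Rax, Zic1, Gbx2 and Lhx5, and strong FM-specific peaks near Irx3, Olig2, Sox1 and Pax7. With 50000 peaks from each list the share was 29.2%, from 21 FM-specific and 51 KO-specific regions, against 50.5% in random lists. The adjusted permutation p was 0.018, not adjusted over the settings tried. A specific region in this setting can overlap a peak of the other full list that is not among its 50000.

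Lists of other cell types the cultures could hold lay inside the central 95% of random lists with the lists as deposited and regions assigned to the nearest gene, and counting 10 kb around genes the extraembryonic list lay at percentile 2.43 (unadjusted permutation p 0.0492, adjusted 0.492). The 15 extraembryonic genes had 93 FM-specific and 57 KO-specific regions (62.0%, percentile 4.76), with Dab2 at 3 and 14 and Tfap2c at 12 and 10. Their direction against random lists turned with 50000 peaks from each list, with 22 FM-specific and 21 KO-specific regions, and among strong specific peaks, with 10 FM and 1 KO. Dab2 and Krt7 (2 and 5) lie on chromosome 15, where KO-specific regions were frequent. Matching random lists on chromosome gave percentile 11.4 for the extraembryonic list. Leaving out chromosomes 12, 15, 18, X and Y gave a share of 69.4% at percentile 10.0. The 15 fibroblast genes, included since the cells were grown on feeder fibroblasts, had 102 and 22 (82.3%, percentile 90.2), of which Twist2 gave 33 and 4 and Fbn1 29 and 1. The 12 housekeeping genes had 39 and 18 (68.4%, percentile 22.7) and the 12 genes of unrelated organs 39 and 16 (70.9%, percentile 37.1).

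With the lists as deposited none of the 10 gene lists passed the adjustment, with the lowest adjusted permutation p at 0.477 for the mesoderm and extraembryonic lists. The unadjusted permutation p was 0.0478 for mesoderm and 0.0954 for the extraembryonic genes. The counts of named genes also moved with 50000 peaks from each list. Lef1 then had 6 FM-specific regions of 11 specific ones, Gsc 5 of 9, Cxcr4 1 of 2, Nog 1 of 3, Kdr 0 of 2, Irx3 2 of 8 and Six3 1 of 3, and Skil had 1 of 1.

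**Figure D3:**
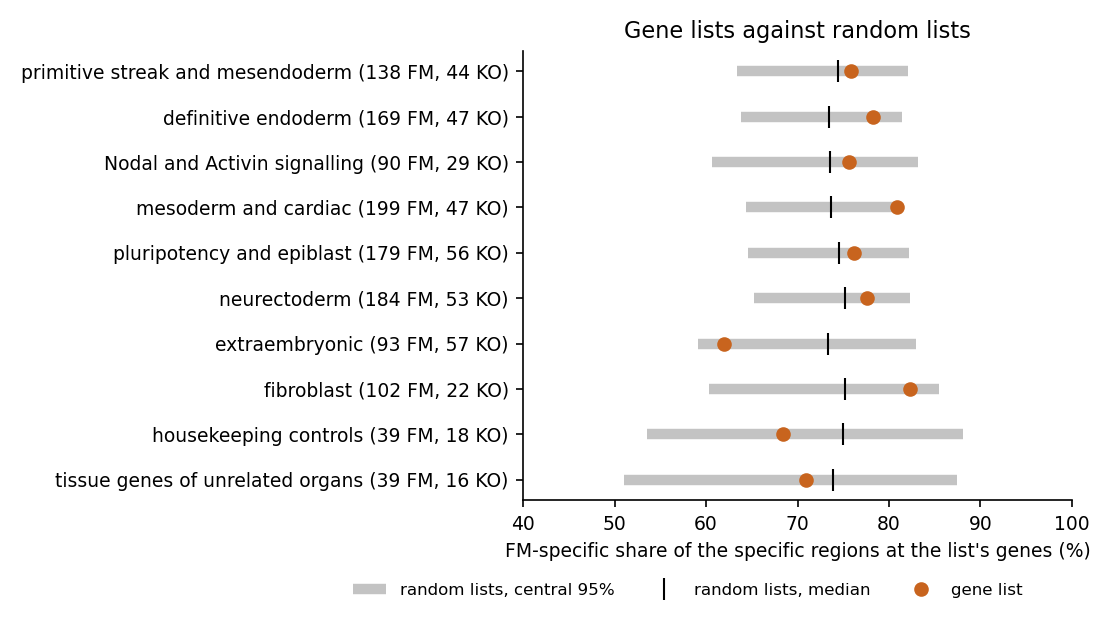
FM-specific share of the specific regions at the genes of each list (x axis, percent; orange points, with the counts of specific regions beside the names), with the median (black tick) and central 95% (grey bar) of 10000 matched random lists. The mesoderm list at 80.9% lies just past the upper end of its bar, at percentile 97.6, and the extraembryonic list at 62.0% lies toward the lower end.

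Specific peaks lay near gene ends less often than shared ones. Of the shared peaks, 16.8% in the FM list and 16.7% in the KO list had their summit within 1 kb of an end of a protein-coding gene, compared with 4.74% (interval 4.61 to 4.87) of FM-specific and 4.62% (interval 4.41 to 4.84) of KO-specific peaks. Shared peaks were more often highly significant, and the comparison was not matched on significance. With 50000 peaks from each list the gene end shares were 37.4% (FM) and 37.3% (KO) of shared peaks. They were 7.78% of FM-specific and 7.15% of KO-specific peaks. Gene bodies held 55.4% of FM-specific and 49.0% of KO-specific peaks with the lists as deposited, and 39.8% and 46.4% were intergenic.

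Among genes outside the fixed lists with at least 5 specific regions, the 12 that deviated most toward each list were mostly long genes. The ranking, by the binomial probability of the split, favours genes with many specific regions, and their lengths were not compared with those of other genes. Toward FM, Plxna4, a semaphorin receptor subunit, had 81 FM-specific and 2 KO-specific regions, and Runx2, the osteoblast transcription factor, had 89 and 4. Galnt18, Abcc4, Tenm4, Supt3, Mgmt, Srgap1, Cfap61, Dab1, Erg and Rcan2 followed, with 92.2% to 100% FM-specific. With 50000 peaks from each list the share was 50% at Dab1 (2 of 4), 60% at Abcc4 (6 of 10) and Tenm4 (9 of 15), 66.7% at Supt3 (8 of 12) and 93.3% at Runx2 (14 of 15). Runx2, Supt3 and Rcan2 lie together on chromosome 17 between 43801352 and 45119294. Runx2 and Supt3 overlap from 44777118 to 44814797, and regions there were counted for both. Toward KO, Rims2, a presynaptic scaffold gene, had 1 FM-specific and 41 KO-specific regions, and Catsperb, a sperm calcium channel subunit, had 1 and 39. Stk3, Vps13b, Tmem117, Oxct1, Zfpm2 and Mucl2 were, with Rims2, the 7 of these 12 genes on chromosome 15. Zfp978, Nsf, Rabgap1l and Gphn completed the KO side, Nsf and Rabgap1l with 0 and 16 each. The median gene length was 294 kb toward FM and 365 kb toward KO.

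The FM-specific peaks of highest fold lay on chromosome 4 at 122122756 to 122123162 (fold 19.1) and 122455130 to 122455490 (fold 18.5), with no protein-coding gene within 100 kb. The next were inside Gnb1l (16: 18533107 to 18533416, fold 10.3), 13.0 kb from Abcb11 (fold 8.12) and 26.8 kb from Mid1 on X (fold 6.94). The KO-specific peaks of highest fold lay on Y at 142750 to 143560 (fold 10.0), inside Pcca (14: 122568868 to 122569218, fold 9.82), inside Commd10 (18: 46997721 to 46998347, fold 9.32), on chromosome 18 at 55939379 to 55939719 (fold 9.01) and on Y at 261050 to 261454 (fold 8.80).

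Chromosomes differed in the ratio of KO to FM peaks. The ratio was 0.676 over all chromosomes and 0.568 to 0.735 on 16 autosomes, but 0.994 on chromosome 15, 0.895 on chromosome 18 and 0.807 on chromosome 12. On X it was 0.839, from 968 and 1154 peaks, and on Y 1.65, from 66 and 40 peaks, where 6 regions were FM-specific and 32 (84.2%, interval 68.7 to 94.0) KO-specific. KO-specific regions were 50.1% (interval 48.9 to 51.3) of the specific regions on chromosome 15, 43.6% (42.2 to 45.1) on chromosome 18 and 36.5% (35.6 to 37.4) on chromosome 12, against 26.8% over all. X had 1.19 FM and 1.00 KO peaks per protein-coding gene, and the autosomes 9.90 and 6.68, with 21.6 and 17.4 on chromosome 12. Among 426 windows of 5 Mb with at least 50 specific regions, 33 had more KO-specific than FM-specific regions, of which 17 were on chromosomes 12, 15 or 18. The highest KO-specific share was 96.4%, in the first 5 Mb of chromosome 15 (3 FM-specific and 81 KO-specific regions). Such shares were not particular to that chromosome. The first 5 Mb of chromosome 14 had 94.1% (3 and 48), and 15 to 20 Mb of chromosome 5 had 83.1% (14 and 69). The lowest share was 9.94%, at 40 to 45 Mb of chromosome 17.

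**Figure D4:**
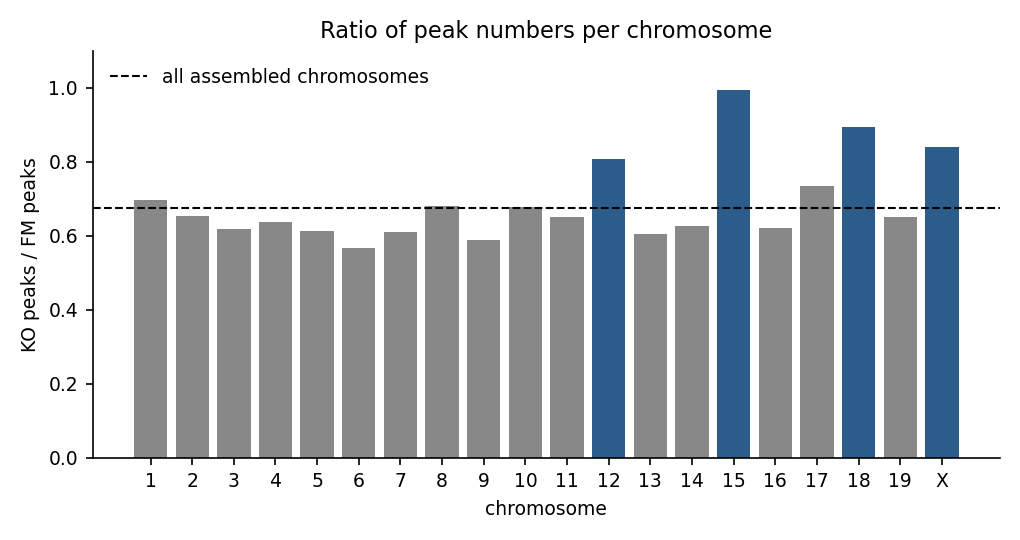
Ratio of the number of KO peaks to the number of FM peaks (y axis) on each autosome and X (x axis), with the ratio over all assembled chromosomes, 0.676, as a dashed line. Y, with few peaks, is not drawn, and chromosomes 12, 15, 18 and X, in blue, lie at 0.807, 0.994, 0.895 and 0.839.

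**Figure D5:**
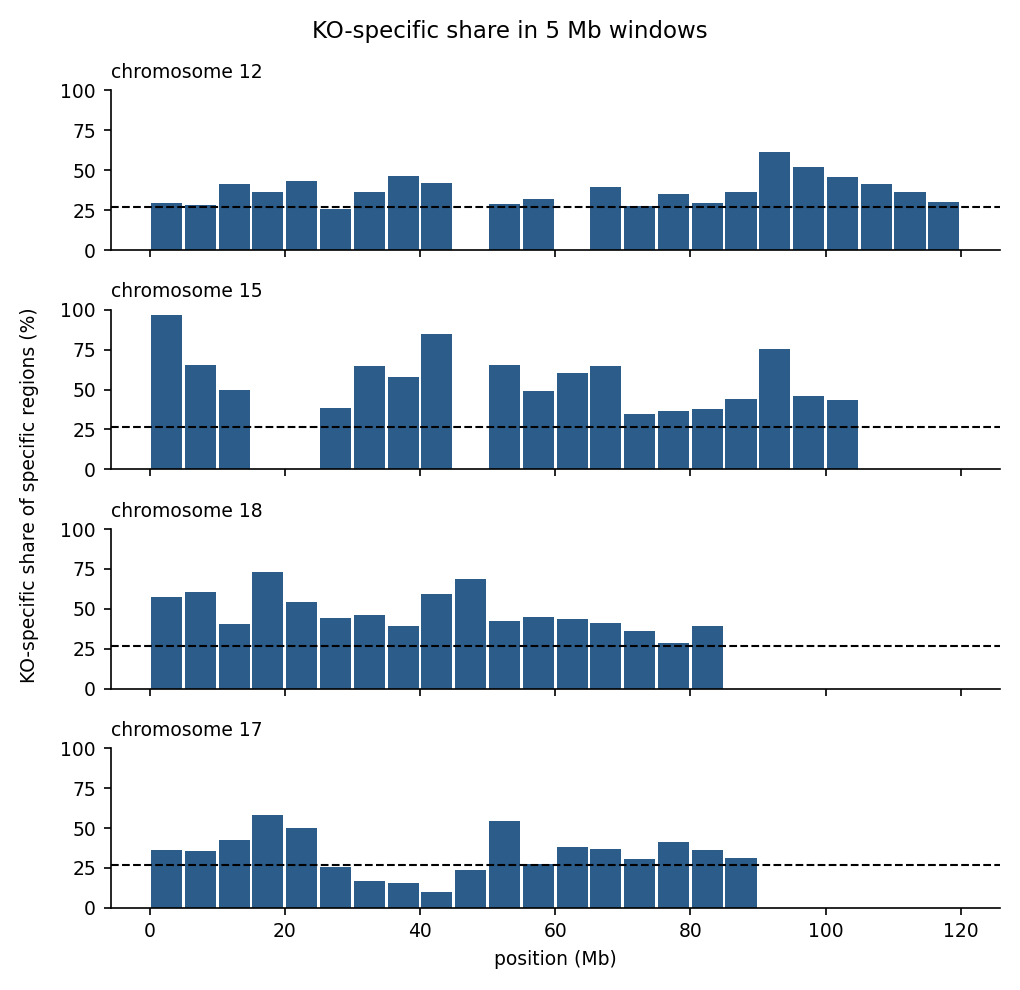
KO-specific share of the specific regions (y axis, percent) in 5 Mb windows along chromosomes 12, 15, 18 and 17 (x axis, position in Mb), with the share over all chromosomes, 26.8%, as a dashed line; windows with fewer than 50 specific regions are left blank. Shares on chromosome 15 reach 96.4%, and the window at 40 to 45 Mb of chromosome 17 is at 9.94%.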

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

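All tests in this part were chosen only after the results were seen. Peaks on unplaced sequences, outside the compared chromosomes, numbered 130 in the FM list and 187 in the KO list; they appear here as signal in data that the comparisons did not use.

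FM-specific regions outnumbered KO-specific ones 2.73 times. Deeper sequencing of the FM libraries is argued against by the recovered background, which was 1.01 times as high in the KO list as in the FM list, if both were called with the same extension. Copy differences of chromosomes 12, 15, 18, X and Y are argued against as well, as 76.0% of specific peaks were FM-specific without them. A candidate explanation is that KO reads were concentrated in strong peaks and FM reads spread over many weak ones. Among the shared peaks 11.3% in the KO list and 8.11% in the FM list had −log10 q of at least 50, a ratio of 1.39. Against the other full list, though, FM-specific peaks remained the majority at −log10 q of at least 5 (74.2%) and 10 (63.1%) and were 23.0% at 20. Whether such a spread of reads comes from the quality of the libraries or from the state of the cells, Mixl1 induction included, stays open, with 1 list per group.

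KO-specific regions were frequent on chromosomes 15, 18 and 12. In 7031 regions with −log10 q of at least 50 in both lists, the median log2 pileup against the other autosomes was 0.056 in the FM list and 0.36 in the KO list on chromosome 15, a difference of 0.30 (bootstrap interval 0.24 to 0.39), and the difference was 0.27 (0.21 to 0.36) on chromosome 18, which may reflect more DNA copies in the KO cells or fewer in the FM cells. A change at a minority of sites on chromosome 15 is argued against, because 84.5% of these regions ranked higher within the KO list than within the FM list, and on the 16 other autosomes 38.0% to 56.9% did. On chromosome 12 the difference of 0.072 (0.016 to 0.145) lay within the −0.09 to 0.10 of the other autosomes, so a copy difference there cannot be told apart from none. On X the difference was −0.012 (−0.089 to 0.086), though 66.3% (interval 56.1 to 75.6) of its 98 regions ranked higher within the KO list. On Y, with 32 KO-specific and 6 FM-specific regions, pileups were not compared. Chromosome 12 stood above the other autosomes in both lists, at 0.19 in FM and 0.26 in KO, as did chromosome 17 at 0.17 and 0.25. A difference of 3 copies to 2 in every cell would give 0.58, and neither DNA input nor single libraries were analysed here, so a gain in part of the cells or libraries and a broad regulatory change both stay open.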

How the results depend on the processing

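The settings with −log10 q of at least 10 or 20 against the other full list, without chromosomes 12, 15, 18, X and Y, with chromosome-matched random lists and with 2.5 kb around gene ends were added after the data were seen. No paired analysis was possible because there is 1 peak list per group, and the replicate numbers that the labels give the libraries do not appear in the lists, and leaving out single libraries was not possible for the same reason. The motif scan, its GC matching and the promoter classes were not run.

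The shares of FM peaks shared, of KO peaks shared and of specific peaks that were FM-specific were 49.2%, 72.5% and 73.2%. They were 37.4%, 55.3% and 67.4% with a reciprocal overlap of 0.5, and 41.8%, 61.9% and 69.3% with summits within 250 bp. Keeping only peaks with −log10 q of at least 5 in both lists gave 48.2%, 70.4% and 72.1%. With a fold of at least 5 they were 93.4%, 52.1% and 7.15%, and with 50000 peaks each 64.7%, 64.3% and 49.7%, which by construction removes the difference in length. With each row counted they were 56.9%, 77.6% and 73.8%. For peaks with −log10 q of at least 10 set against the other full list they were 87.6%, 91.2% and 63.1%, and with at least 20 99.03%, 97.0% and 23.0%. These are not comparable with the settings of −log10 q of at least 5, of fold of at least 5 and of 50000 peaks, where both lists were filtered. Against the other full list, 74.2% of specific peaks were FM-specific at −log10 q of at least 5. Without the 5 chromosomes the 3 shares were 47.7%, 74.3% and 76.0%. Thinning to equal background, which removed 207 KO peaks, and using all sequences kept the 3 shares within their intervals. The FM-specific and KO-specific peaks near gene ends were 11.5% and 10.5% within 2.5 kb and 7.78% and 7.15% with 50000 peaks. The KO to FM ratio relative to all chromosomes went from 1.47 to 1.38 on chromosome 15 and from 1.19 to 1.02 on chromosome 12 with 50000 peaks.

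The gene lists' differences from random lists, in percentage points of FM-specific share, changed sign as follows. Counting 10 kb around genes gave −0.301 for the streak, −0.179 for neurectoderm and 0.634 for unrelated organs, and counting within 20 kb −4.16 for the streak and 0.0506 for unrelated organs. With −log10 q of at least 5 in both lists the streak was at −6.27, Nodal at −2.88 and neurectoderm at −4.29. With 50000 peaks the streak was at −6.55, endoderm −13.2, Nodal −11.2, mesoderm −14.0, neurectoderm −21.4 and extraembryonic 1.16. With −log10 q of at least 10 against the other full list the streak was at −37.3, Nodal −26.7, mesoderm −6.67 and neurectoderm −19.3. In that setting extraembryonic was at 24.2 and housekeeping at 28.6, the last from 1 FM peak and 0 KO peaks. Chromosome-matched random lists gave 4.96 for housekeeping and 6.81 for unrelated organs, and leaving out the chromosomes −0.195 for the streak, −0.557 for pluripotency and −0.157 for neurectoderm. Of these, neurectoderm with 50000 peaks and the streak at −log10 q of at least 10 had adjusted permutation p of 0.018 and 0.024. They were the lowest of all lists and settings, and the adjustment covered the lists of a setting, not the settings. Apart from the streak at −log10 q of at least 10, the cause was not tested. For 121 named genes, 445 of 671 values under alternatives lay within the binomial interval of the main value and 226 outside. The depth in reads is unknown, and weak peaks near the threshold limit the specific sets.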

Other observations

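The tests on strong specific peaks were chosen after the results were seen, and the share over all specific regions was planned. Strong specific peaks of both lists, with −log10 q of at least 10, lay near the same gene at Eomes, Fgf8, Lhx1 and Lef1 of the streak list, and also at Sfrp1, Pax7, Sall4, Cubn and the unrelated-organ gene Mbp. At Fgf8, a growth factor gene of the streak, the FM peak at 19: 45720567 to 45720913 and the KO peak at 45722834 to 45723196 were neighbours. At Eomes the KO peaks were 73.0 kb and 72.0 kb and the FM peak 20.2 kb from the gene. Extraembryonic genes had 10 strong FM-specific peaks and 1 KO-specific peak, or 90.9% against 66.7% in random lists (adjusted permutation p 0.42), whereas over all their specific regions the FM share was 62.0%, at percentile 4.76. Of the strong FM peaks, 3 lay at Lama1, a basement membrane laminin gene, and others near Elf5, Ascl2, Krt7 and Sox7. Pluripotency genes had 14 and 5, and fibroblast genes 6 and 1, of which Twist2 held 3 FM peaks.

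Strong specific peaks at primitive streak genes were mostly KO-specific, 12 to 5, while genome-wide 63.1% of such peaks were FM-specific. A single gene of the list is argued against, since leaving out each gene in turn kept the list at or under percentile 0.34 of random lists, and so are copy differences of chromosomes 12, 15, 18, X and Y, at percentile 0.07 without them. Distance is argued against too, because peaks within 20 kb, 1 FM and 8 KO, were at percentile 0.005. These percentiles are not adjusted and reuse the same 5 FM and 12 KO peaks or parts of them. They therefore add no separate support for the pattern and do not address chance. But the threshold matters. With −log10 q of at least 5 against the other full list the streak genes had 51 FM and 23 KO peaks, at percentile 11.7. At 20 or more, only the FM peaks near Eomes (28.4) and Lhx1 (23.0) and the KO peak near Fgf8 (26.2) remained. Genome-wide, 200 FM-specific and 668 KO-specific peaks reached 20. The KO majority at streak genes thus came from peaks with −log10 q between 10 and 20. The values are not shown to be particular to streak genes, since Nodal genes had 4 FM and 6 KO strong peaks and neurectoderm genes 9 and 10, also below the 66.7% of random lists, and neither the difference between lists nor an effect of Mixl1 was tested.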
